A study of Mus musculus with 2 samples.

How the data were processed

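The data come from an RNA immunoprecipitation and sequencing experiment on nucleolin, an RNA-binding protein that is abundant in the nucleolus, in mouse CD4+ T cells taken from spleen and activated with antibodies against CD3 and CD28. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a small RNA kit from Illumina. The series has 2 samples, 1 nucleolin immunoprecipitate and 1 input, with no replicate of either. The series' design text speaks of an IgG immunoprecipitate, while the second label reads as an input, and that sample is called the input here. Per the submitters' processing notes the genome build was mm9, whereas the design text names mm10. The aligner, the rule that chose transcripts for the deposited table and the settings of its search are not given in the sources used here.

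The values analysed are in 1 table of BLAST alignments that the authors deposited for the series as a whole. Each of its 101 rows pairs a mouse transcript with a mature miRNA. Per the file headers, identity is in percent, and the score and bit score are those of the alignment program, as are the E-values. These columns belong to no single sample. The table holds no read counts, so the depth of both libraries is unknown, and the planned nucleolin over input ratio could not be computed. No p-value between the 2 samples exists. Presence in the table is therefore all that can be said of a transcript, and its relation to the input is not known.

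Transcript identifiers were looked up in GENCODE M21, an annotation of GRCm38 (mm10), and 101 of 101 matched transcripts of type miRNA. Positions below are on GRCm38, counted from 1, and come from this match, not from the authors' alignments. Mature miRNA sequences and positions were taken from the RefSeq annotation of the same assembly, which holds 1970 mature mouse miRNAs. The searched sequence of each row was rebuilt as the first 60 nt of the miRNA gene from its lowest genomic coordinate, read on the plus strand, or the whole gene where it is shorter. Its length equalled the query length in 101 of 101 rows, and in 100 of the 100 rows with a RefSeq mature sequence the bases at the stated positions equalled the miRNA.

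Each locus was placed in a host gene, defined as a gene that contains the whole locus. Only protein-coding, lincRNA, processed transcript, antisense and sense intronic genes could be hosts. Genes on the same strand were taken first, protein-coding genes next and then the shortest. A locus inside no such gene, or only partly overlapping one, was counted as having no host gene. A locus was counted in a coding exon, UTR or exon of a noncoding transcript when the larger part of the miRNA gene lay there in any transcript of the host, and at an exon-intron boundary when a smaller part of more than 3 nt did. All of these count as exonic. A locus was called at an intron end when its own end lay within 3 nt of a splice site. A locus can meet both definitions in different transcripts of 1 gene.

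The miRNAs named were chosen by a rule fixed before the data were examined. It takes all members of 4 lists of miRNAs (T cell activation, T cell quiescence, reported as nucleolin-dependent, and other cell types) that the table holds, the 10 miRNAs with the best alignment by length, identity, E-value, bit score and name, the 5 miRNAs with the most query transcripts, and the 10 transcripts with the most miRNAs. The host genes named, and any other locus, were chosen after their values were seen. The shares of matches on the plus strand and of 5p arms were tested with exact two-sided binomial tests against 50%. These describe the table, since its rows are not biological replicates.

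The comparison with other annotated loci was also chosen after the table was seen. Its background is the 1241 of 2202 GENCODE miRNA transcripts whose first 60 nt hold at least 19 nt of an annotated mature miRNA on the gene's own strand, 19 nt being the shortest alignment in the table. Of the 101 listed loci 100 are in it, and miR-1194, for which RefSeq gives no mature sequence, is not. Odds ratios are conditional estimates with exact 95% intervals and two-sided Fisher's exact tests. Stratified odds ratios are Mantel-Haenszel estimates over 5 bins of GC content. Medians were compared with two-sided permutation tests of 100000 resamples. Benjamini-Hochberg adjustment was applied within each family of tests, namely 9 features of loci, 4 further splits, 3 continuous measures, 21 chromosomes and 4 miRNA lists. Loci are not independent, since neighbouring miRNA genes share transcripts.

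The odds ratio estimates were tested on simulated data, with 200 random listings of the 1241 loci per setting. For exonic loci with a true odds ratio of 4 and no GC effect the median Fisher estimate was 4.07. With a GC effect added it was 5.19, and the stratified estimate 4.13, so unstratified odds ratios can be too high where GC content differs. With a true odds ratio of 1 and a GC effect, the unstratified test called 45.5% of the listings and the stratified test 5.5%. Other settings tried were limits on identity, alignment length and E-value, the best alignment per query, joined miRNA names and the use of every row. Those for the background comparison were added after the table was seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9. The single-sample sequencing reads were not used here, and the details of 1 listed locus are not reported here.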

Results

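The experiment asked which RNAs are bound by nucleolin in activated CD4+ T cells. Small RNA libraries were made from 1 nucleolin immunoprecipitate and 1 input of mouse spleen CD4+ T cells stimulated through CD3 and CD28. The values available are a list of 101 miRNA gene transcripts, each aligned to a mature miRNA, without read counts. Depth is unknown, there are no replicates, and no transcript can be compared between nucleolin and input. The results describe which miRNA loci the list holds and where these lie in the genome, on GRCm38.

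The list held 101 transcripts of 101 miRNA genes, which matched 98 distinct mature miRNAs. Of these genes 90 lay inside a protein-coding gene on the same strand, such as those of miR-6973a-5p in Ltb, which encodes lymphotoxin beta, and miR-7081-3p in Dnmt1, the maintenance DNA methyltransferase. Every alignment had 100% identity, but both sequences of a pair are reference sequences, not reads. The alignments were 19 to 25 nt long, with a median of 22 nt, and E-values ran from 1.01e-09 to 3.84e-06. In 98 rows the whole mature miRNA was matched and in 3 rows a part of it. No miRNA was listed with both of its arms, so joining names to the miRNA number also gave 98.

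Of 59 miRNAs on the 4 lists fixed in advance, 2 were present. These were miR-29a, 1 of 20 members of the T cell quiescence list, and miR-326, 1 of 22 members of the T cell activation list, a miRNA known from work on Th17 cells. Membership was judged by the miRNA name without the arm. For both miRNAs the other arm lay outside the searched part, so it could not have been listed. The listed miR-29a-3p (UAGCACCAUCUGAAAUCGGUUA) comes from Mir29a, whose mature sequence lies on chromosome 6 from 31062673 to 31062694 on the minus strand, in no annotated host gene. The listed miR-326-5p (GGGGGCAGGGCCUUUGUGAAGGCG) lies on chromosome 7 from 99552288 to 99552311 on the plus strand, in an intron of Arrb1, which encodes beta-arrestin 1. The activation miRNAs miR-155, miR-17 and miR-21a and the lymphocyte miRNAs miR-150, miR-181a and miR-142a were not listed. Of 6 miRNAs reported as nucleolin-dependent, among them miR-15a, miR-16 and miR-221, 0 were listed, and of 14 miRNAs typical of other cell types, such as miR-451a, miR-223 and miR-122, 0 were listed.

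All 59 list members had an annotated locus with a match in the part of the gene that was searched, 80 loci in all, of which 2 were listed. The odds ratio of being listed for these loci against the others was 0.278 (exact 95% interval 0.0326 to 1.07; two-sided Fisher's exact test, p = 0.0568), so this difference did not pass the threshold. For the separate lists the adjusted p was 0.966 for T cell activation, 0.966 for T cell quiescence, 1 for the nucleolin-dependent miRNAs and 0.966 for other cell types.

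The longest alignment was that of miR-669k-5p (UGUGCAUGUGUGUAUAGUUGUGUGC), which matched over 25 nt in Gm22677 on chromosome 2, from 10465778 to 10465802 on the plus strand. This miRNA also had the most query transcripts, 3, the others being Gm22072 with 23 nt and Gm25680 with 21 nt. All 3 genes lie in an intron of Sfmbt2, which carries a large miRNA cluster, and 102 of the loci that could have been listed lie in that cluster. Next by alignment came 8 miRNAs matched over 24 nt. In introns of protein-coding genes these were miR-326-5p, miR-3076-5p in Tkt, which encodes transketolase, miR-6900-5p in Ndufa10, a subunit of respiratory complex I, miR-6937-5p in Adi1 and miR-7089-5p in Cdc25a, a phosphatase of the cell cycle. The other 3 were miR-5046 in a UTR of Rps6ka4, miR-7037-5p in Ints1, a subunit of the Integrator complex, and miR-7115-5p in Arrb2, both in exons of noncoding transcripts of these genes. The tenth miRNA by rank was miR-7649-3p, with 23 nt.

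By number of query transcripts, miR-692 followed miR-669k-5p with 2, Gm22133 in the coding sequence of Ftl1, the ferritin light chain, and Gm22774 on the opposite strand of an intron of Tulp4. Each other miRNA had 1, and by name the next were miR-1194, miR-1199-3p and miR-1306-3p. Each transcript was paired with 1 miRNA, so the order of transcripts by number of miRNAs is that of their identifiers. The first 10 were Mir7-1, Mir326, Mir425, Mir212, Mir29a, Gm22133, Gm22774, Mir707, Mir704 and Mir678. Mir7-1 lies in an intron of Hnrnpk, which encodes an RNA-binding protein, and its listed product was miR-7a-1-3p (CAACAAAUCACAGUCUGCCAUA), on chromosome 13 from 58392800 to 58392821 on the minus strand. Mir425, in an exon of a noncoding RNA gene, was listed with miR-425-5p, and Mir212, in an intron of another, with miR-212-5p.

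The matches lay on the plus strand in 41 of 101 rows (40.6%, exact 95% interval 30.9% to 50.8%; exact two-sided binomial test against 50%, p = 0.0728). The orientation of the match equalled the strand of the miRNA gene in 101 of 101 rows. Each query was the reference sequence of a miRNA gene, so this says nothing of the strand of the sequenced RNA. The plus-strand share is that of the genes, and 745 of the 1241 loci that could have been listed lie on the plus strand. Among the 80 distinct miRNAs whose name carries an arm, 41 were 5p (51.2%, exact 95% interval 39.8% to 62.6%; exact two-sided binomial test, p = 0.911). The arm went with the strand of the gene. Of the rows with an arm, 35 of 35 on the plus strand named the 5p arm, against 8 of 47 (17%) on the minus strand (two-sided Fisher's exact test, p = 9.55e-16). Each searched sequence was the first 60 nt of the gene from its lowest genomic coordinate, or the whole gene where it was shorter. On the plus strand that part begins at the 5′ end of the gene, and on the minus strand at its 3′ end. The 8 minus-strand genes with a listed 5p arm were 58 to 65 nt long, so that this part covered nearly all of the gene. The searched part thus largely set which arm could match. The p-value for arm and strand is therefore no measure of an arm preference in the RNA.

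**Figure D1:**
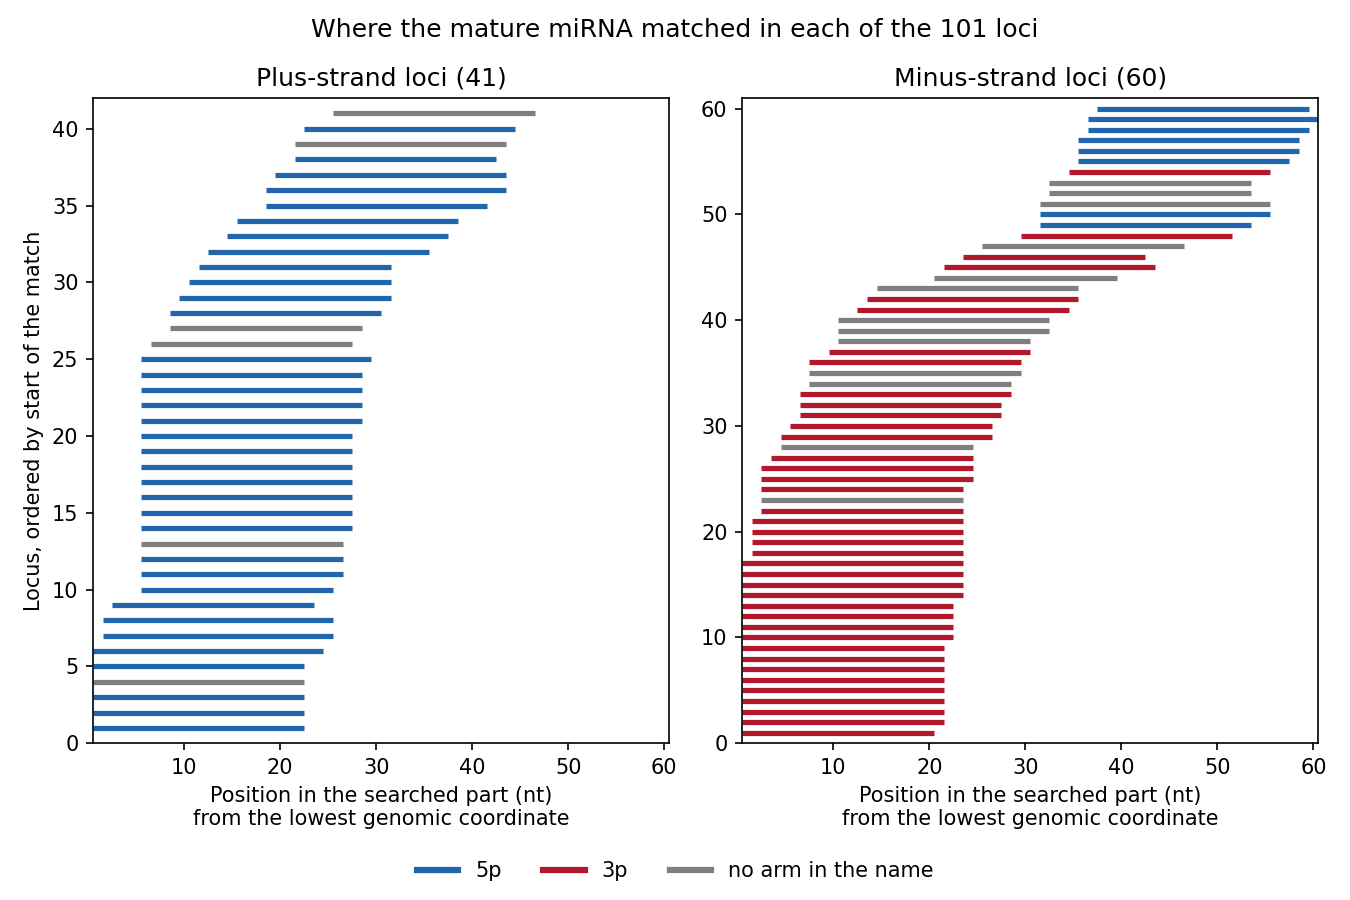
Position of the matched mature miRNA (x axis, nt from the lowest genomic coordinate of the miRNA gene) in each of the 101 loci (y axis, ordered by start), for 41 plus-strand and 60 minus-strand genes. Blue lines are 5p arms, red lines 3p arms and grey lines miRNAs with no arm in the name, and the 8 blue lines on the minus strand lie toward the far end.

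Listed loci lay in exons and at the ends of introns more often than the other miRNA loci that the same search could have matched. The miRNA gene overlapped an exon in 47 of 100 listed loci and in 182 of 1141 others (odds ratio 4.67, exact 95% interval 2.98 to 7.28; two-sided Fisher's exact test, adjusted p = 1.94e-11). An end of the gene lay within 3 nt of an intron end in 53 of 100 listed loci and in 176 of 1141 others (odds ratio 6.17, exact 95% interval 3.95 to 9.67; adjusted p = 2.30e-15). Loci with no host cannot lie in an exon or at an intron end. Among loci inside any gene the odds ratio was 3.31 (exact 95% interval 2.1 to 5.2) for exons and 4.43 (exact 95% interval 2.81 to 7.01) for intron ends. Among loci inside a protein-coding gene on its own strand the odds ratio for intron ends was 3.58 (2.21 to 5.84). Over all loci, stratified by quintiles of GC content, the odds ratio for intron ends was 4.07. Type of host and GC content were not held fixed together. Of 26 loci in coding exons 10 were listed (38.5%, 95% Wilson interval 22.4% to 57.5%), of 57 in UTRs 13 were (22.8%), and of 320 with no host gene 3 were (0.938%). Among loci in introns, with at most 3 nt in an exon, 37 of 190 at an intron end were listed (19.5%) against 13 of 502 away from the ends (2.59%; odds ratio 9.06, exact 95% interval 4.57 to 19.1; adjusted p = 1.70e-12). Together, 84 of 100 listed loci lay in an exon or at an intron end, against 335 of 1141 others (odds ratio 12.6, exact 95% interval 7.20 to 23.4; adjusted p = 1.35e-26). These tests compare loci within 1 list with the annotation and say nothing of the input.

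**Figure D2:**
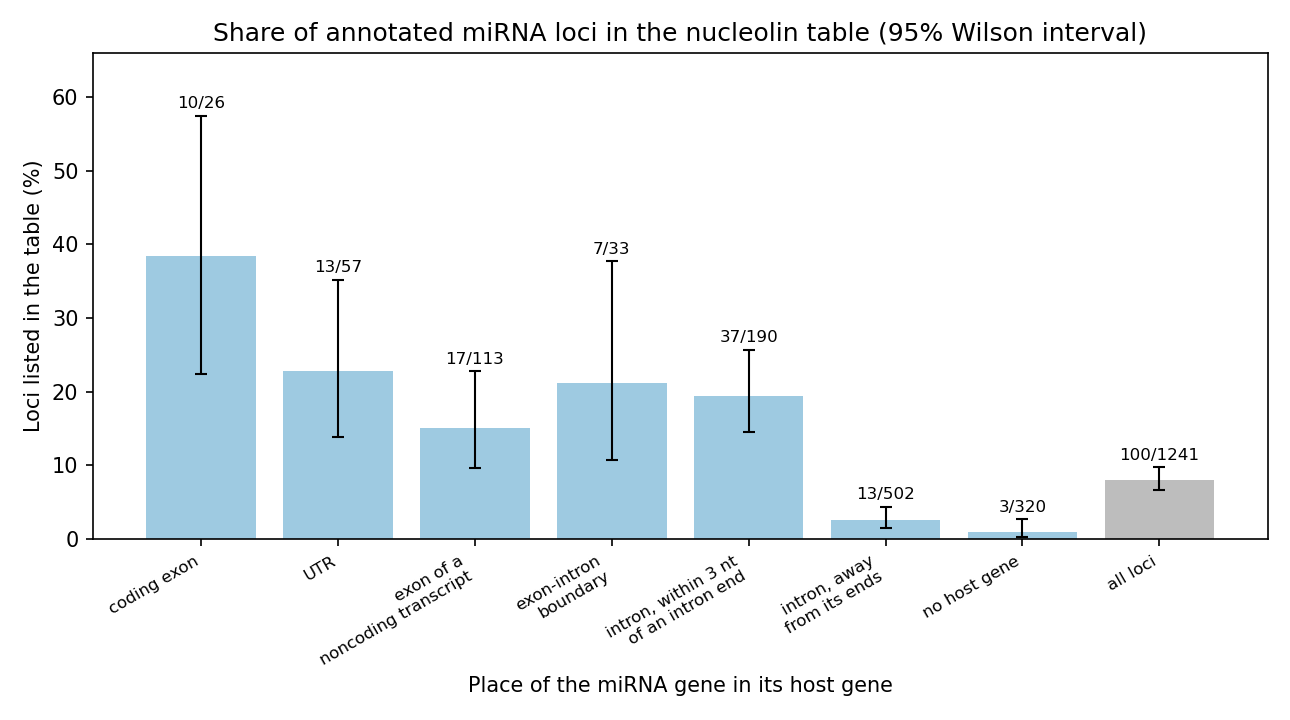
Percentage of annotated miRNA loci that were listed (y axis) by place of the miRNA gene in its host (x axis), with 95% Wilson intervals and the listed and total loci above each bar. Coding exons stand at 38.5% and loci with no host gene at 0.938%, and all loci together at 8.06%.

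The host was a protein-coding gene on the same strand in 89 of 100 listed loci and 594 of 1141 others (odds ratio 7.44, exact 95% interval 3.91 to 15.6; two-sided Fisher's exact test, adjusted p = 1.92e-13). Over all 101 loci, 95 lay in a host on the same strand, 3 on the opposite strand and 3 in no host. There were 92 distinct host genes. Hosts with more than 1 listed locus were Sfmbt2 with 3 and Cmip, Ddx39b, Dgcr8 and Skiv2l with 2 each. Dgcr8 encodes the partner of Drosha in pri-miRNA processing, and its 2 loci, which give miR-1306-3p and miR-3618-3p, lie in its coding exon and UTR.

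The following hosts were picked after their values were seen, and stand for no group of genes. On chromosome 17, listed genes lie in Ltb and Ddx39b. Mir6973a, from 35194972 to 35195049 on the plus strand, ends where an exon of Ltb begins, and gives miR-6973a-5p (UACGGUGGGAGGGGUGGAGUUG). Mir6975, from 35244075 to 35244135, ends at the last base of an intron of Ddx39b, a helicase of splicing and mRNA export, and Mir8094, from 35251289 to 35251405, overlaps a coding exon of the same gene. In all, 7 listed loci filled an intron of their host, against 13 of 1141 other loci (odds ratio 6.51, exact 95% interval 2.15 to 18.1; two-sided Fisher's exact test, adjusted p = 0.000652). Among loci inside a protein-coding gene on its own strand that odds ratio was 3.80 (exact 95% interval 1.25 to 10.6).

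**Figure D3:**
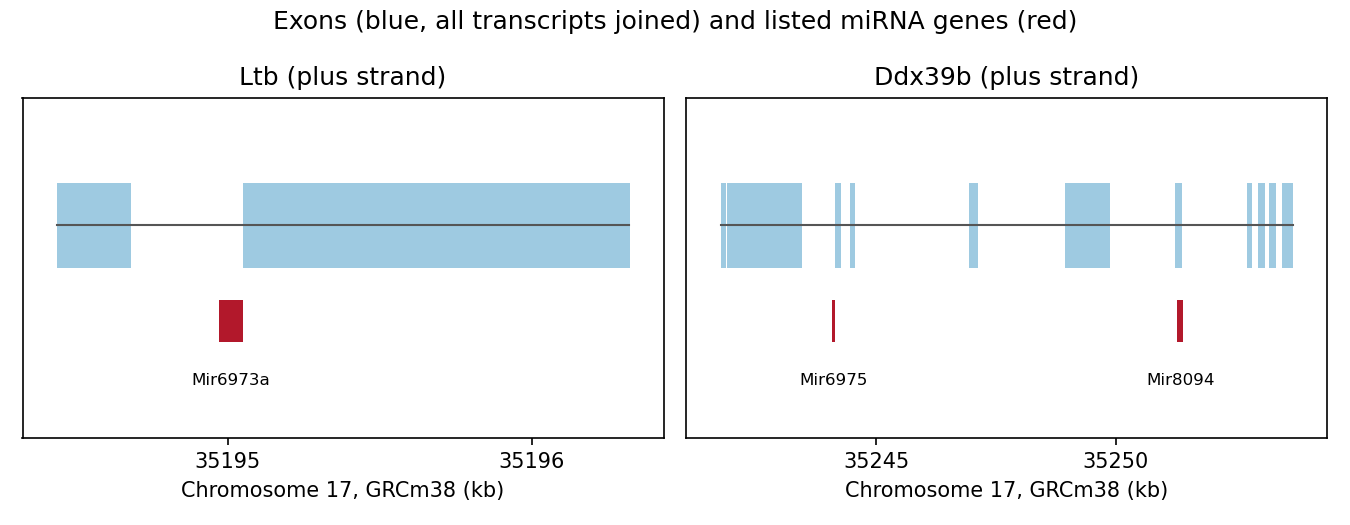
Exons of Ltb and Ddx39b, all transcripts joined (blue), and listed miRNA genes in them (red), along chromosome 17 (x axis, kb on GRCm38, to a different scale in each panel). Mir6973a and Mir6975 end where an exon begins, and Mir8094 overlaps an exon.

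Listed miRNA genes were richer in GC, with a median of 57.5% (quartiles 52.6% to 62.9%, 100 loci) against 50% (42.2% to 57.1%, 1141 loci), and shorter, with a median of 73 nt against 83 nt. Listed loci in introns lay in shorter introns, with a median of 808 nt over 50 loci against 8729 nt over 642 loci. Many of the latter share 1 intron of Sfmbt2, and without clusters of at least 10 loci the medians were 719 nt over 47 loci and 5210 nt over 536 loci (two-sided permutation test, p = 2e-05). The intron taken was the shortest around the locus in any transcript of the host. Of the listed loci in introns, 37 of 50 lay at an intron end, against 153 of 642 others. Intron length was not tested apart from this, so it is no separate trait of the listed loci. The permutation tests gave an adjusted p of 3e-05 for GC and for intron length, from p = 2e-05, the smallest that 100000 resamples can give, and an adjusted p of 0.00048 for gene length. Minus-strand genes made up 59 of 100 listed loci and 437 of 1141 others (odds ratio 2.32, exact 95% interval 1.50 to 3.61; two-sided Fisher's exact test, adjusted p = 0.000106). Chromosome 17 had more listed loci than the rest of the genome, 11 of 51 (odds ratio 3.40; Fisher's exact test, adjusted p = 0.0205), and chromosome 2 had fewer, 5 of 185 (odds ratio 0.281; Fisher's exact test, adjusted p = 0.0205). Chromosome 3 had 0 of 48 (Fisher's exact test, p = 0.0281, adjusted p = 0.0983), and no other of the 21 chromosomes passed the adjusted threshold. The chromosome tests take loci as independent. On chromosome 2, 102 of the 185 loci lie in the Sfmbt2 cluster, and on chromosome 17 Skiv2l and Ddx39b hold 2 listed loci each. Most of the listed loci on chromosome 17 also lie in 1 stretch, from 34841809 to 35960814. These are Mir6971, Mir6970, Mir6973a, Mir6974, Mir6975, Mir8094 and Mir877.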

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

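The limit of 22 nt and the alternatives for the 3 odds ratios were chosen after seeing the data. The planned limits on identity, alignment length and E-value and the best alignment per query each removed 0 of 101 rows, so they test nothing. Joining arms and copies left 98 miRNAs, and using every row gave 40.6% plus-strand matches and 52.4% 5p arms. With alignments of at least 22 nt, 63 rows and 62 distinct miRNAs were left, fewer because 38 rows are shorter, and 2 list members were still found. The plus-strand share was then 47.6% and the 5p share 62.5%, and neither passed the threshold (exact two-sided binomial tests, p = 0.801 and p = 0.0814). Over 8 alternatives the odds ratio for exons ranged from 3.31 (inside any gene) to 6.12. Over 7 alternatives that for intron ends ranged from 3.58 (inside a protein-coding gene on its own strand) to 6.51, and it was 4.07 over GC quintiles of all loci. Over 6 alternatives that for minus-strand loci ranged from 1.90 to 2.42. Each kept its direction and stayed past the threshold, with p at most 9.21e-08, 0.00058 and 0.00389. No paired analysis was possible because each group has 1 sample and the table has no values per sample. The nucleolin over input ratio and its 2 alternatives, another scaling and no count minimum, were not run, since no read counts were at hand. Depth is unknown, so absence from the list cannot be read as absence from nucleolin.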

Other observations

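The tests of the clusters, of the listed arm and of list loci in exons were chosen after the results they measure had been seen. Those of GC content for exons and intron ends and the other tests of the list members were chosen before that. But they too were chosen after the data were first seen. For minus-strand loci no prediction on GC content or clusters was written. All were run on the same list, and no biological explanation was tested, since the input has no values here.

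The 4 largest clusters of miRNA loci, those with at least 10 loci, gave few listed loci. On chromosome 2 the cluster in Sfmbt2 gave 3 of 102, the 2 clusters on chromosome 12 gave 0 of 15 and 0 of 36, and that on chromosome X gave 0 of 19. Such clusters held 3 of 100 listed loci and 169 of 1141 others (odds ratio 0.178, exact 95% interval 0.0357 to 0.546; two-sided Fisher's exact test, adjusted p = 0.000504). Of 112 loci on the opposite strand of their host gene 3 were listed, against 94 of 809 on the same strand (odds ratio 4.77 for the same strand, exact 95% interval 1.54 to 24.0; adjusted p = 0.00168).

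Listed loci lay more often in exons and at intron ends than other loci. They were also richer in GC, but within quintiles of GC content the common odds ratio was still 3.77 (95% interval 2.43 to 5.84) for exons and 4.07 (2.60 to 6.36) for intron ends, so GC content is not the whole cause. The large clusters among the other loci are not either, since without them the odds ratios were 4.46 (2.83 to 7.03) and 5.55 (3.53 to 8.78). Fragments of host gene transcripts in the library, a preference of nucleolin for these transcripts and higher transcription of these hosts in T cells were not tested and stay open without counts.

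The listed arm followed the strand of the gene. A search limited to the first 60 nt from the lowest coordinate accounts for which arm was named. Of the 100 loci with a mature sequence, the listed miRNA was the only longest match in that part at 97. At 3 it was tied for longest, and at 0 another match was longer. That part held both whole arms at 19 loci, of which 3 had arms of equal length, and at the other 16 the longer arm was the listed one at 16. An arm preference in the RNA itself was not tested. Among unlisted loci the longest match in the same part was 5p at 504 of 518 plus-strand loci and 96 of 336 minus-strand loci, a split of the same kind. The arms named in the list thus do not show which arm was bound. Listed loci also held a larger share of minus-strand genes, with an odds ratio of 2.08 over quintiles of GC content (95% interval 1.36 to 3.17) and of 2.08 without the large clusters (exact 95% interval 1.33 to 3.29), so neither is the whole cause.

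Only 2 of 80 loci of the fixed lists were listed, and over all loci this did not pass the threshold. The limited search does not account for the low number of list miRNAs found, 2 of 59. Loci with a list member anywhere in the gene had a mature miRNA in the searched part at 81 of 81. That was more often than at other annotated loci, with a lower 95% bound of the odds ratio of 5.91. The 80 loci and their odds ratio were already limited to loci with such a match, so this says nothing of them. Among loci inside a gene on its own strand, list members had an odds ratio of being listed of 0.132 (exact 95% interval 0.00324 to 0.787; two-sided Fisher's exact test, unadjusted p = 0.0147). This rests on 1 listed locus, and neither type of host nor place was held fixed. It therefore cannot exclude lying inside or outside a gene as the cause. In exons, 0 of 27 list loci were listed against 47 of 202 others (upper exact 95% bound of the odds ratio 0.509, two-sided Fisher's exact test, p = 0.00185). In exons of noncoding transcripts alone it was 0 of 23 against 17 of 90 (two-sided Fisher's exact test, p = 0.0214). The type of host gene was not held fixed in these exon tests, and neighbouring loci can share 1 transcript. The exon tests therefore cannot exclude place or type of host as the cause. Over all places the question stays open. The common odds ratio stratified by place was 0.289 (95% interval 0.075 to 1.11), against 0.278 without strata, but the places differed. In introns away from their ends, 1 of 30 list loci was listed against 12 of 472 others. With no host gene it was 1 of 23 against 2 of 297. No list locus lay at an intron end, where 37 of 190 others were listed. For the T cell activation list alone and the T cell quiescence list alone no difference passed the threshold, and the rule behind the list of transcripts is not known, so a shortfall of T cell miRNAs is not established.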
